A study of Danio rerio with 18 samples.

How the data were processed

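Total RNA from whole zebrafish embryos at 4 h post-fertilisation was extracted with a spin-column kit (Direct-zol), and libraries were made with the Nextera XT kit on a nanolitre liquid handler at reduced volumes, per the labels' protocols. This kit does not mark the strand, so reads of a gene and of an antisense partner cannot be told apart. Each of the 18 libraries came with a table of whole-number read counts per gene, deposited by the authors and used here as raw counts. A second deposited table per library holds TPM values (transcript abundances scaled by gene and by library), a unit inferred from the values, since all columns sum to the same total and their ratio to the counts differs between genes. The tool bcl2fastq 2.20 and the genome build danRer11 are named in the submitters' processing notes. The aligner, the counter and its strand setting, and the annotation release are not given in the sources used here. Genes that share reads with near-identical copies, or that overlap others, are therefore uncertain in their counts.

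Groups were taken from the sample titles: 8 cocktails of 25 gRNAs and 1 RfxCas13d control, with 2 libraries each. Of the rows in each count table, 4 name no gene (unmapped, multimapping, ambiguous and no feature). They were left out of library sizes and tests and made up 22.6% to 55.5% of the reads in the table. Gene counts per library ran from 2544027 to 4864939 with a median of 3264108. Gene names are those in the files; 10 symbols written like dates were matched to their gene by identifier, 80 genes had no name, and 561 names were borne by several identifiers.

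Counts were scaled by the trimmed mean of M values and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, robust) with 1 coefficient per group over all 18 libraries, so that groups of 2 shared an estimate of the spread (common biological coefficient of variation 0.280). Genes were kept by edgeR's filter with a minimum count of 10, which left 14514 of 32520. Each cocktail was compared with the control and with the mean of the 7 other cocktails, and the mean of all cocktails with the control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold, or with no fold minimum for the mean of all cocktails. The 16 gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, adjusted over lists, or over lists and cocktails together. List medians per library are log2 CPM with a prior count of 2, minus the mean of the controls. Groups at 0 counts were given a floor of 3 counts over their 2 libraries, and ratios to groups with 1 to 3 counts an exact 95% interval.

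The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Per cocktail against the control, the rule took the 10 largest decreases and the 4 largest increases among called genes with both cocktail libraries beyond both controls and a mean of at least 5 CPM in the higher group. For the mean of all cocktails it took 10 decreases and 10 increases with all 16 cocktail libraries beyond both controls, and for recurrence the 15 genes lower in the most cocktails, ties ordered by mean log2 change. Members of the gene lists were named as examples, called ones with large changes first and otherwise those highly expressed. Genes named against the other cocktails were chosen after their values were seen, by adjusted p among genes lower against both references.

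The tests were tried on simulated counts with the library sizes of the real libraries. Each gene had its mean over all libraries and the same spread in every group. The real replicates of Cocktails 1 and 3 lay further apart (SD of the median gene 0.380 and 0.399 log2 units, against 0.189 in Cocktail 6). The shares below therefore do not cover groups of unequal spread. In the comparison of Cocktail 1 with the control, 44%, 68% and 86% of genes lowered by 1.5, 2 and 3 log2 units were called, and 9 unchanged genes of 14007 tested. Against the other cocktails the shares were 58%, 80% and 90%, with 9 unchanged genes called. For the mean of all cocktails 39% of genes lowered and 38% of genes raised by 1 unit were called, and 5 unchanged genes of 14004. The alternatives were DESeq2 1.42.0, RLE size factors, no filter (24993 genes tested), the replicate number as a block, only the libraries of the groups compared, other fold minimums, each library left out in turn, and limma on log2(TPM + 1) for genes with a TPM of at least 1 in 2 libraries (19867 genes), a scale that understates the change of low genes. Thinning to equal depth and leaving out Cocktail 1 replicate 1 from the list tests were added after seeing the data. Overlaps between cocktails, which share their controls, were set beside 20 simulations of unchanged groups. No coordinates are given, since no genome of this build was used here. The result of 1 gene list is not reported here.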

Results

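RNA was sequenced from whole zebrafish embryos at 4 h post-fertilisation, a stage at which the embryo's own genome is being transcribed while many maternal mRNAs are still present. RfxCas13d is a CRISPR nuclease that cuts RNA matched by its guide RNA (gRNA). The study asked how well models built outside the embryo predict which mRNAs a gRNA depletes inside it. For this, 200 gRNAs were split over 8 cocktails, each with 25 gRNAs with an amount stated as 10 pg per embryo. Whether this amount is per gRNA or per cocktail, and what the control embryos received besides RfxCas13d, are not given in the sources used here. Each cocktail and the RfxCas13d control had 2 libraries, which makes 18 libraries in 9 groups. The genes matched by the gRNAs and the predicted scores are not given in the sources used here, so no gene below is named as one that a gRNA was meant to hit. Gene counts per library ran from 2544027 in Cocktail 8 replicate 1 to 4864939 in control replicate 1, and 14514 of the 32520 genes had enough counts to be tested. The labels do not say whether replicates came from separate clutches or injections, so all p-values measure only the spread between these samples, which may be technical.

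The share of reads that mapped nowhere moved with the groups. It was 10.4% ± 0.539 (SD, n = 2) in the control and 29.7% ± 7.01 (SD, n = 16) in the cocktail libraries. The cocktail libraries lay between 21.6% and 47.3%, all above both controls (two-sided exact permutation p = 0.00654, the smallest that the 153 splits allow). This test takes the 18 libraries as independent. They come in 9 groups of 2 with 1 control group, so its p may be too small. Reads from mitochondrially encoded genes made up 8.61% to 14% of gene counts, and the controls, at 10.4% and 10.4%, lay inside this range. On the first principal component, which held 31.0% of the variance, the controls scored 87.2 and 89.0. Cocktail 1 replicate 1 scored -106, and the other cocktail libraries scored between -42.3 and 27.1. On the third component, with 7.38% of the variance, Cocktail 3 replicate 2 scored highest at 56.1, followed by Cocktail 1 replicate 2 at 31.7. Correlations of log2 CPM, counts scaled to library size, between replicates ran from 0.877 in Cocktail 1 to 0.962 in Cocktail 6, and every pair differed by more than sampling noise (chi-square per degree of freedom of at least 3.48), with the widest gaps in Cocktail 1 (30.9) and Cocktail 3 (22.6).

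The mean of the 8 cocktails was first set against the control, to see what the cocktails had in common. Genes of the embryo's outermost epithelium and of its yolk syncytial layer were among those that fell most. The mean level of krt5, a keratin, was 418 ± 37.2 CPM (SD, n = 2) in the control and 19.7 ± 16.6 CPM (SD, n = 16) in the cocktail libraries (log2 fold change -4.92 ± 0.29 SE, adjusted p = 6.51e-08). For evpla, a plakin that links keratins to cell junctions, the change was -5.09 ± 0.29, and for mttp, which loads lipid onto apolipoprotein B, it was -4.39 ± 0.31. In the other direction, buc, the organiser of the Balbiani body in the oocyte, rose by 2.42 ± 0.21, from 181 ± 13.7 CPM to 988 ± 236 CPM. The same libraries differed in unmapped reads, 29.7% in the cocktails against 10.4% in the control.

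Among the genes taken by the naming rule, the largest decreases were those of fetub, znf750, anxa1c, si:ch211-232i5.1, slco1d1, abcc6b.2, thsd7bb, hkdc1, rbm47 and cdh6. The mean CPM of fetub, a fetuin, was 33.6-fold lower than in the control, with 0 counts in 4 of the 8 cocktails. For cdh6, a cadherin, the mean was 28.1-fold lower, for slco1d1, an organic anion transporter, 21.9-fold, and for rbm47, an RNA-binding protein, 14.1-fold. Among the largest increases, hivep3b rose from 1.56 ± 0.0753 CPM to 17.1 ± 7.19 CPM (log2 3.40 ± 0.70). The others with more than 3 counts in the controls were cbx7b, a Polycomb protein (3.89 ± 0.72), traf1, a signalling adaptor (3.53 ± 0.69), zgc:113090 (3.78 ± 0.63) and chst12a, a carbohydrate sulfotransferase (3.42 ± 0.76). Of the genes with 3 or fewer control counts, the ratios with their 95% counting intervals were vasna (44.3-fold, 12.3 to 366), ptdss1b (39.4-fold, 10.9 to 325), eya4 (22.2-fold, 7.58 to 107), gcdhb (16.5-fold, 5.64 to 80.0) and si:busm1-57f23.1 (21-fold, 5.81 to 173). These intervals, and the floors used below for counts of 0, cover counting error only. The call of gcdhb was lost without control replicate 1 (adjusted p = 0.138) and that of chst12a without control replicate 2 (0.0545), and DESeq2 did not call hkdc1 or thsd7bb (adjusted p = 0.375 and 0.376).

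In all, 1970 genes were lower and 2185 higher in the cocktails (adjusted p under 0.05, no minimum fold). In 1514 of the lower and 1599 of the higher genes, all 16 cocktail libraries lay beyond both controls. Over all genes tested, 1781 lay wholly below and 1729 wholly above, where chance gives a share of 0.00654 in each direction if the libraries are taken as independent. The counts fell to 876 lower and 1013 higher without control replicate 1, and to 890 and 1009 without control replicate 2. The share of higher genes among the calls was 52.6%, against 67.0% when log2(TPM + 1) values were tested with limma, a scale on which the median gene lay 0.14 log2 units higher. It was 45.8% with RLE size factors (2322 lower and 1962 higher) and 45.8% with no filter on low counts (2431 and 2055), so the direction with more calls turned with the setting; fold changes here are therefore relative to the scaling used.

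Gene lists fixed before the data were examined were tested in the same contrast, and 12 of the 16 measured genes of the enveloping layer, the embryo's outermost epithelium, fell while none rose. The largest falls among those with counts in every cocktail were those of evpla (-5.09 ± 0.29), krt5 (-4.92 ± 0.29), cyt1 (-4.57 ± 0.39), krt97 (-4.35 ± 0.28) and cyt1l (-4.08 ± 0.68) (log2 ± SE). The keratin krt4 fell by 2.57 ± 0.78, a call lost without either control library (adjusted p = 0.181 and 0.178; DESeq2 gave 0.0597 and limma on TPM 0.197), and grhl3 (-0.64 ± 0.88) did not pass. Without Cocktail 1 replicate 1, a choice made after seeing the data, krt4 was at -2.45 ± 0.12 and grhl3 at -0.53 ± 0.12. The enveloping layer list had a median log2 fold change of -2.43 (camera adjusted p = 4.00e-19, and adjusted p = 0.0458 with an estimated correlation). Adjusted over the list alone, 12 genes were also called. Of the 8 genes of the yolk syncytial layer, a multinucleate layer of the yolk cell, 6 fell, among them mttp (-4.39 ± 0.31), gata6 (-3.46 ± 0.24) and hnf4a (-2.41 ± 0.48), while mxtx2 was at 0.50 ± 1.00. Its median was -2.43 (adjusted p = 4.54e-11; adjusted p = 0.113 with an estimated correlation; also 6 adjusted over the list alone). The call of hnf4a was lost without either control library (adjusted p = 0.0517 and 0.0504) and by limma on TPM (0.122). In the fit without Cocktail 1 replicate 1, hnf4a was at -2.30 ± 0.17. Counts in lists without 1 library, and changes of genes without Cocktail 1 replicate 1, here and below, were added after seeing the data. Without Cocktail 1 replicate 1, 8 of 9 yolk syncytial genes were lower and 1, mxtx2 (0.61 ± 0.19), higher. With all libraries, no gene of either list was higher at an unadjusted p under 0.05 in edgeR, or called higher by DESeq2 or by limma on TPM, and the same held for the mesendoderm, ventral, dorsal and ribosomal lists.

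Of 14 mesendoderm and Nodal genes, 6 fell and none rose, or 11 adjusted over the list alone. Among them were gata6 (-3.46 ± 0.24) and gata5 (-2.44 ± 0.29), which also stand in the yolk syncytial list, tbxta (-2.89 ± 0.48), the brachyury gene, sox32 (-2.44 ± 0.35), an endoderm factor, and fscn1a (-1.29 ± 0.14). The T-box gene tbx16 had -2.15 ± 0.78 (adjusted p = 0.0668) and did not pass over all genes. Without Cocktail 1 replicate 1, tbx16 was at -2.04 ± 0.11. The list's median was -1.58 (adjusted p = 1.84e-07; adjusted p = 0.423 with an estimated correlation). In the ventral BMP and Wnt list 5 of 10 genes fell, also 5 adjusted over the list alone, among them bmp4 (-2.01 ± 0.38) and bmp7a (-2.28 ± 0.48), both BMP ligands (median -1.67, adjusted p = 0.00104; adjusted p = 0.474 with an estimated correlation). Of the dorsal organizer list 4 of 9 fell, also 4 adjusted over the list alone: chrd (-2.51 ± 0.50), a BMP antagonist, fgf8a (-2.04 ± 0.38), foxa2 (-1.69 ± 0.38) and gsc (-1.41 ± 0.43). Its median was -1.41, or -1.19 with genes at 0 counts set at their bound (camera adjusted p = 0.00767, and adjusted p = 0.494 with an estimated correlation). Without Cocktail 1 replicate 1, bmp7a was at -2.18 ± 0.13, chrd at -2.39 ± 0.19 and gsc at -1.31 ± 0.25. Without control replicate 1, bmp7a, chrd and gsc were not called (adjusted p = 0.0562, 0.0580 and 0.178), and without control replicate 2, bmp7a and gsc were not (0.0746 and 0.149); limma on TPM did not call gsc either (0.0838). In the mesendoderm list 10 genes were lower and 1, ndr1 (0.71 ± 0.26), higher without Cocktail 1 replicate 1, and 11 and 0 without its replicate 2. The ventral count was 8 and 9 without these libraries in turn, 2 without control replicate 1, 2 without control replicate 2, and 3 by DESeq2 and by limma on TPM. It was also 3 without Cocktail 2 replicate 1, Cocktail 4 replicate 1, Cocktail 5 replicate 2, either library of Cocktail 6, Cocktail 7 replicate 1 or either library of Cocktail 8. The dorsal count was 2 without control replicate 1.

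Oocyte and germ plasm genes moved the other way: 12 of 19 rose and none fell, the same counts adjusted over the list alone, while 2 were lower at an unadjusted p under 0.05 in edgeR and 0 by DESeq2 or limma. They included buc (2.42 ± 0.21), tdrd6 (2.37 ± 0.38), a Tudor protein of germ granules, btg4 (2.30 ± 0.26), zar1l (1.33 ± 0.23) and dazl (1.17 ± 0.23). The germ-line helicase gene ddx4 (-0.30 ± 0.14) did not pass. The list's median was 0.80 (adjusted p = 9.75e-06; adjusted p = 0.0510 with an estimated correlation). Its count of higher genes was 6 without control replicate 1, and 2 genes were lower without Cocktail 1 replicate 2. Maternal regulators of genome activation went both ways: 5 of 11 fell, led by pou5f3 (-1.21 ± 0.14), ctnnb1 (-0.93 ± 0.16) and ybx1 (-0.92 ± 0.16), and 3 rose, eomesa (1.53 ± 0.19), sox19b (1.33 ± 0.17) and smad2 (0.93 ± 0.17), with the same counts adjusted over the list alone. The homeobox gene nanog was at 0.25 ± 0.15, and the list as a whole did not pass (median -0.37, adjusted p = 0.483).

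Of the cytosolic ribosomal protein genes, 13 of 79 fell and none rose, or 9 adjusted over the list alone, with rps7 at -1.26 ± 0.23 and rpl4 at 0.03 ± 0.15; the list had a median of -0.40 (adjusted p = 4.61e-05; adjusted p = 0.644 with an estimated correlation). The remaining lists did not pass as lists, with the counts of called genes the same adjusted over the list alone unless given. Ubiquitous early zygotic genes had 4 lower and 1 higher of 17, with pcdh8 (-4.19 ± 0.58) and osr1 (-1.95 ± 0.30) lower and otx1 (1.59 ± 0.23) higher (median -0.81, adjusted p = 0.0991). Only 7 of 19 interferon and RNA sensing genes could be tested, of which stat1a (2.78 ± 0.75) and irf7 (1.78 ± 0.58) rose and isg15 was at -0.03 ± 0.97 (median 0.81, adjusted p = 0.249). Without control replicate 2 neither stat1a nor irf7 passed (adjusted p = 0.134 and 0.0740), and without control replicate 1 irf7 did not (0.288). The lower counts of the ribosomal list were 1 and 4 without control replicates 1 and 2, 26 without Cocktail 1 replicate 2 and 20 without Cocktail 3 replicate 2. Those of the ubiquitous zygotic list were 2 and 2 without the controls in turn and 10 and 11 without those of Cocktail 1, with 2 higher in the fit without its replicate 1. Without Cocktail 1 replicate 2, 1 of 11 interferon genes was lower.

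Among heat shock and unfolded protein genes, 6 of 16 fell, including atf4a (-1.95 ± 0.38) and hspa8 (-0.77 ± 0.15), and 2 rose, including hspa5 (1.06 ± 0.14), the chaperone BiP of the endoplasmic reticulum (median -0.33, adjusted p = 0.373). The mRNA decay and small RNA list had 7 lower and 2 higher of 22 genes called, with cnot7 (1.86 ± 0.30), a deadenylase, higher and ythdf2 (-0.89 ± 0.15), an m6A reader, lower (median -0.12, adjusted p = 0.258). The cell cycle list had 9 lower and 6 higher of 26, or 11 and 6 adjusted over the list alone. In it the maternal cyclin A gene ccna1 rose by 1.02 ± 0.14, ccnb2 rose by 0.96 ± 0.15, and ccne2 had -2.26 ± 0.29 (median -0.12, adjusted p = 0.378). Of 13 mitochondrially encoded genes edgeR called 0, with 3 higher and 0 lower at an unadjusted p under 0.05; DESeq2 called 0, and limma on TPM called 4 higher. Their median was -0.02, their mean 0.13 and the test pointed upward (adjusted p = 0.647). Of 20 later tissue and blood markers only 3 were measurable, with elavl3 lower (-1.85 ± 0.64; median -0.59, adjusted p = 0.378), a call lost without either control library (adjusted p = 0.111 and 0.30) and by limma on TPM (0.0689). With limma on TPM the lower counts were 3 in the heat shock, 3 in the mRNA decay and 4 in the cell cycle list. Without control replicate 1 the lower and higher counts of these lists were 3 and 1, 3 and 1, and 3 and 2, and without control replicate 2 they were 2 and 2, 2 and 1, and 1 and 4. Of the mitochondrially encoded genes, 3 and 2 were higher without replicate 1 and replicate 2 of Cocktail 1, 2 without Cocktail 3 replicate 1 and 1 without Cocktail 8 replicate 2.

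Set against the control one by one, the enveloping layer, yolk syncytial layer, mesendoderm and ventral lists fell and the oocyte list rose in all 8 cocktails, by camera with its preset correlation. None of these calls held with an estimated correlation, where the lowest value of any list in any cocktail was adjusted p = 0.130 with an estimated correlation. The mean enveloping layer median of a cocktail ran from -5.07 in Cocktail 1 (-7.03 and -3.11 in its libraries) to -1.59 in Cocktail 6, on a log2 scale against the mean of the controls. With Cocktail 1 replicate 1 left out, the lowest was Cocktail 4 at -3.38. The ribosomal list passed in 7 cocktails (not Cocktail 7) and the dorsal list in 4 (Cocktails 1, 4, 5 and 8). The ubiquitous zygotic list passed in Cocktail 1 alone, and the mRNA decay list in Cocktail 3 alone, which does not show that these cocktails differed from the rest. In fits with 1 library fewer, added after seeing the data, the ribosomal pass of Cocktail 1 was lost without its replicate 1 (adjusted p = 0.559; medians -0.86 and 0.06 in its libraries), and that of Cocktail 3 without its replicate 1 (0.632; medians -0.65 and 0.20) or control replicate 1 (0.102). The ubiquitous zygotic pass was lost without Cocktail 1 replicate 1 (0.0851), and the mRNA decay pass without Cocktail 3 replicate 2 (0.514; medians -0.02 and -0.88) or control replicate 1 (0.0532). The dorsal pass was lost without replicate 2 in Cocktail 4 (0.0831) and in Cocktail 8 (0.0831), and the ventral pass without replicate 1 in Cocktails 2 and 3 (0.0777 and 0.228) and without replicate 2 in Cocktails 7 and 8 (0.0777 and 0.0655). The enveloping layer, yolk syncytial, mesendoderm and oocyte lists passed in all 8 cocktails whichever of a cocktail's or the control's libraries was left out. In all, 54 of 128 list tests passed with camera's preset correlation and 0 with an estimated one. Differences between cocktails were tested by permuting the 16 cocktail libraries over the 8 cocktails. They exceeded those between replicates for the mesendoderm (adjusted p = 0.0201), yolk syncytial (0.0201), enveloping layer (0.0420) and oocyte lists (0.0420) of the 16 lists (permutation test, Benjamini-Hochberg).

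Within Cocktail 1 the libraries differed widely. The enveloping layer median was -7.03 in replicate 1 and -3.11 in replicate 2, the yolk syncytial median -7.05 and -3.22, and the mesendoderm median -5.38 and -2.24. For the ubiquitous early zygotic genes it was -6.0 in replicate 1, -0.42 in replicate 2, and between -1.06 and -0.22 in all 15 cocktail libraries other than replicate 1. The oocyte medians were closer, at 1.27 and 1.00. Leaving out Cocktail 1 replicate 1, a choice made after seeing the data, 8 lists passed for all cocktails and 67 of 128 tests for single cocktails. With an estimated correlation these numbers were 6 and 43, against 1 and 0 with all libraries. For the mean of all cocktails the enveloping layer list then had a median of -2.32 (adjusted p = 0.00153 with an estimated correlation), the oocyte list 0.79 (0.00196), the mesendoderm list -1.47 (0.00196) and the yolk syncytial list -2.34 (0.00743). The ventral list had -1.59 (0.00961), and the ubiquitous zygotic list, with 10 lower and 2 higher of 18, had -0.72 (0.00961).

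**Figure D1:**
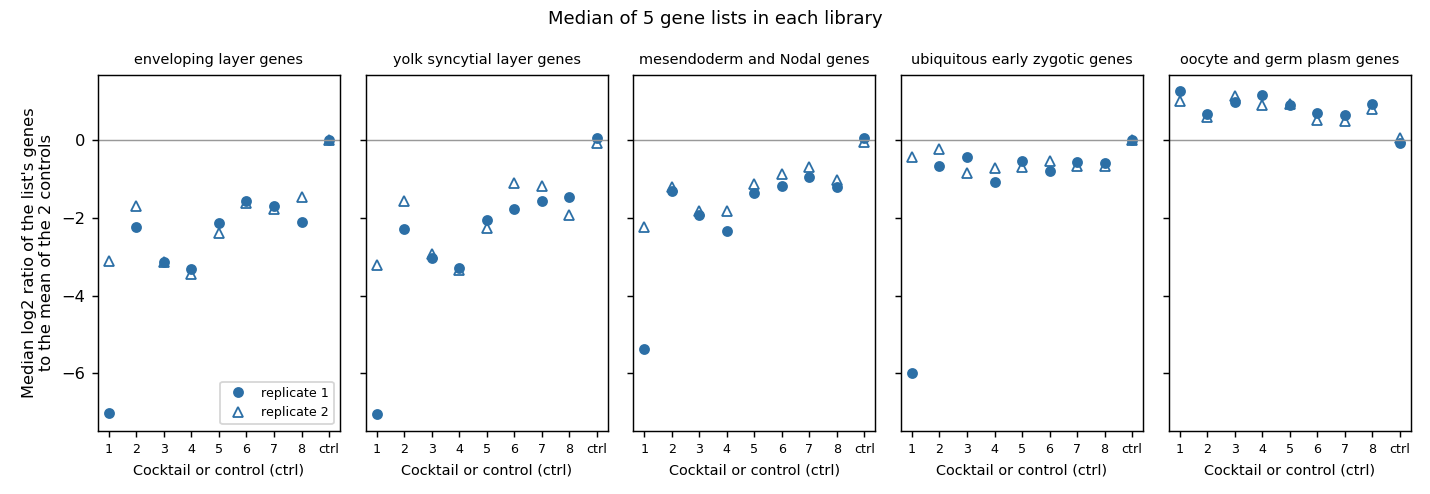
Median log2 ratio of 5 gene lists to the mean of the controls, one point per library (filled circles replicate 1, open triangles replicate 2), by cocktail and control. Cocktail 1 replicate 1 has an enveloping layer median of -7.03 and a ubiquitous early zygotic median of -6.0.

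**Figure D2:**
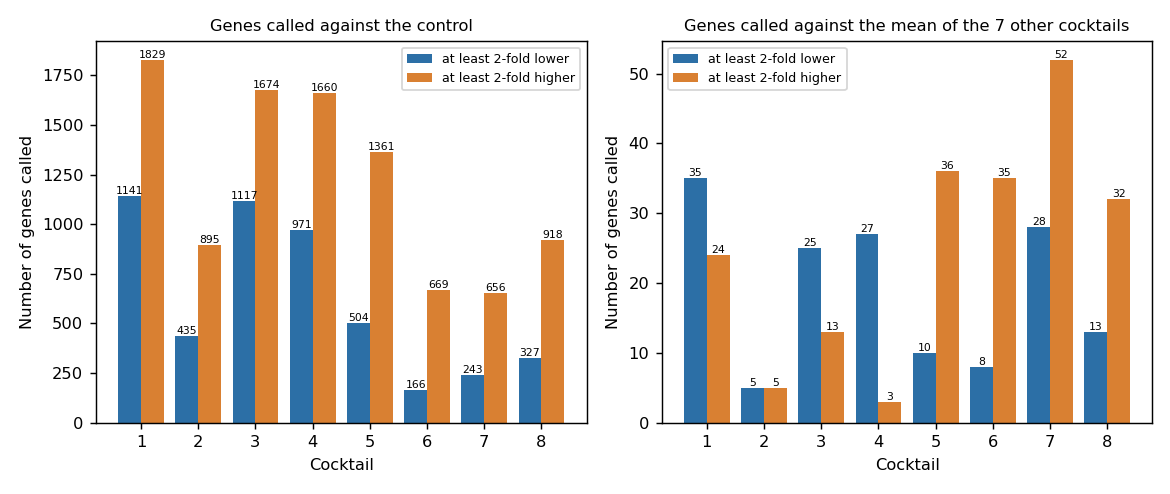
Number of genes called at least 2-fold lower (blue) and higher (orange) in each cocktail, against the control (left) and against the mean of the 7 other cocktails (right). Against the control the lower genes ran from 166 in Cocktail 6 to 1141 in Cocktail 1, and against the other cocktails from 5 in Cocktail 2 to 35 in Cocktail 1. All groups shared an estimate of the spread. With only the groups compared in the fit, lower genes against the control were 708 in Cocktail 1 and 652 in Cocktail 6. They then ran from 621 in Cocktail 7 to 1439 in Cocktail 4, so the order of cocktails depends on the libraries in the fit.

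Each cocktail holds other gRNAs, so each was also compared with the mean of the 7 other cocktails. This contrast leaves out the control libraries, which still entered the filter, the scaling and the shared estimate of the spread. In Cocktail 1, ppp4r2b, a regulatory subunit of protein phosphatase 4, stood at 16.2% of its level in the other cocktails (-2.63 ± 0.20), and its paralogue ppp4r2a at 41.1% (-1.28 ± 0.17). Also lower were papolg (-2.66 ± 0.23), a poly(A) polymerase, drap1 (-1.86 ± 0.15), a repressor of transcription, ctdspl2a (-2.92 ± 0.41), lmnb1 (-1.09 ± 0.16), a nuclear lamin, mier1a (-1.19 ± 0.17) and alg3 (-1.09 ± 0.16), a mannosyltransferase of N-glycosylation (adjusted p at most 0.00136). These genes, and those of the same comparison in the other cocktails, were chosen after their values were seen, as the lowest by adjusted p among genes lower against both references. In all, 35 genes were at least 2-fold lower than in the other cocktails and all 35 of these at least 2-fold lower than in the control too, with a median of 25.3% of the other cocktails. Leaving out replicate 1 gave 10 genes, 8 of them among the 35, and leaving out replicate 2 gave 684. The others of the 10 were sc:d217 (0.41 in replicate 1 and -4.26 in replicate 2) and peli2 (-0.44 and -1.63). Without replicate 1, lmnb1 still passed the adjusted p but fell short of the 2-fold minimum; morc3b (-3.24 ± 0.49) and zgc:153018 (-2.07 ± 0.32) were lost without replicate 1 (adjusted p = 0.0632 and 0.0858). In such fits the lone library is assumed to vary like those of the other groups.

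Against the control, kcnk1a, a potassium channel of the K2P family, had 0 counts in Cocktail 1 and was at least 92.7-fold lower, taking 3 counts over both libraries as the floor. Other genes at 0 counts were slco1d1 (at least 77.3-fold), fetub (at least 67.7-fold), cdh6 (at least 51.9-fold), krt17 (at least 46.9-fold), a keratin, fgf24 (at least 36.1-fold), a fibroblast growth factor, and eve1 (at least 27.7-fold), a homeobox gene for which DESeq2 gave adjusted p = 0.0666. Among the increases were cacng5a (at least 16.8-fold), with 0 counts in the control, and acot18 (88.4-fold, 24.5 to 730.1) and vasna (70.8-fold, 19.6 to 585), with 1 to 3 counts there. In all, 1141 genes were at least 2-fold lower and 1829 at least 2-fold higher. There were 781 lower and 1011 higher genes without Cocktail 1 replicate 1, 1613 and 2155 without its replicate 2, 759 and 1202 without control replicate 1, and 741 and 1201 without control replicate 2. Of the 14 genes named by rule, 13 were called whichever library was left out; 1 without Cocktail 1 replicate 1, 0 without Cocktail 1 replicate 2, 1 without control replicate 1 and 0 without control replicate 2 were lost (adjusted p up to 0.0784).

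Cocktail 2 had 5 genes at least 2-fold lower than the other cocktails, all 5 of them lower than the control as well, at a median of 33% of the other cocktails. The lowest was bckdk (-2.87 ± 0.25), the kinase of the branched-chain ketoacid dehydrogenase, at 13.6%, followed by rpp25l (-2.19 ± 0.23), gbgt1l4 (-1.60 ± 0.25), alg3 (-1.45 ± 0.17) and tarbp2 (-1.18 ± 0.16), a partner of Dicer (adjusted p at most 0.00247). Without replicate 1, 2 genes were called, and alg3, tarbp2 and gbgt1l4 were lost (adjusted p = 0.0507, 0.148 and 0.369); without replicate 2, 4 were called and tarbp2 was lost (0.110).

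Relative to the control, 435 genes were at least 2-fold lower and 895 at least 2-fold higher in Cocktail 2. The largest decreases had 0 counts in the cocktail: add3b (at least 69.4-fold), an adducin of the membrane skeleton, plxnb1b (at least 23.3-fold), a plexin, and atp1b3a (at least 22.8-fold), a subunit of the sodium pump. Among the increases were ptdss1b (59.2-fold, 16.4 to 489), a phosphatidylserine synthase, and acot18 (70.8-fold, 19.6 to 584). The counts were 173 lower and 530 higher genes without Cocktail 2 replicate 1, 171 and 572 without its replicate 2, 173 and 444 without control replicate 1, and 181 and 452 without control replicate 2. Of 14 genes named by rule, 3 (add3b, plxnb1b and ptdss1b) were called whichever library was left out; 9 without Cocktail 2 replicate 1, 9 without Cocktail 2 replicate 2, 11 without control replicate 1 and 9 without control replicate 2 were lost (adjusted p up to 0.221), and limma on TPM did not call plxnb1b (adjusted p = 0.0583).

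In Cocktail 3, bckdk and tarbp2 were lower again, at 12.8% and 18.3% of the other cocktails (-2.97 ± 0.25 and -2.45 ± 0.18). Lower too were ppp4r2a (-2.16 ± 0.19), papolg (-1.88 ± 0.22) and mier1a (-1.82 ± 0.18), which were also lower in Cocktail 1, and stk26 (-2.01 ± 0.18), a kinase, abhd17c (-2.47 ± 0.24), a depalmitoylase, tatdn2 (-2.48 ± 0.29), peli2 (-2.05 ± 0.30) and setdb1b (-1.65 ± 0.23), a histone H3K9 methyltransferase (adjusted p at most 0.000579). In all, 25 genes were at least 2-fold lower than in the other cocktails and 23 of these at least 2-fold lower than in the control too, with a median of 29.4% of the other cocktails. Without replicate 1, 381 genes were called, and without replicate 2, 14, when setdb1b was lost (adjusted p = 0.0534).

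The control comparison of Cocktail 3 gave 1117 genes at least 2-fold lower and 1674 at least 2-fold higher. At 0 counts in the cocktail were fetub (at least 67.4-fold), fgf24 (at least 35.9-fold), afp4 (at least 34.2-fold), a name borne by several genes, rbm47 (at least 25.5-fold), adamts18 (at least 25.1-fold), a metalloprotease, and emilin2b (at least 20.8-fold). The calcium channel subunit gene cacng5a, at 0 counts in the control, was at least 18.6-fold higher, and acot18 (86.8-fold, 24.0 to 717) was higher as well. Leaving out libraries gave 1363 lower and 1655 higher genes without Cocktail 3 replicate 1, 618 and 1213 without its replicate 2, 743 and 1046 without control replicate 1, and 733 and 1065 without control replicate 2. Of 14 genes named by rule, 8 were called whichever library was left out; 3 without Cocktail 3 replicate 1, 5 without Cocktail 3 replicate 2, 4 without control replicate 1 and 2 without control replicate 2 were lost (adjusted p up to 0.137).

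In Cocktail 4 the cell division cycle gene cdca7b stood at 5.52% of the other cocktails (-4.18 ± 0.23), tia1, an RNA-binding protein of stress granules, at 5.59% (-4.16 ± 0.24), and cstf2, a cleavage stimulation factor of mRNA 3' ends, at 5.64% (-4.15 ± 0.28). Also lower were rbm25b (-3.51 ± 0.26), a splicing factor, syncripl (-2.22 ± 0.17), dnajc5ga (-2.54 ± 0.21), rnf128a (-2.66 ± 0.23), golga7 (-2.19 ± 0.24), usp1 (-1.94 ± 0.19), a deubiquitinase, and ilf2 (-1.75 ± 0.19) (adjusted p at most 8.94e-06). For dnajc5ga the controls were low as well, at -1.47 and -1.87 log2 units from the median of the cocktail libraries. Cocktail 4 stood at -2.69 and -2.84, so its gap to the control was smaller than that to the other cocktails. In all, 27 genes were at least 2-fold lower than in the other cocktails and 26 of these at least 2-fold lower than in the control too. The median of these 26 was 20.8% of the other cocktails. The count was 16 without replicate 1 and 15 without replicate 2, and all 10 named genes were called in both fits.

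For Cocktail 4 against the control, b3gnt5a, a glycosyltransferase, had 0 counts and was at least 241-fold lower. The same held for zgc:110333 (at least 139-fold), si:ch211-98n17.5 (at least 95.1-fold), slco1d1 (at least 71.8-fold), fetub (at least 62.8-fold), gcnt7 (at least 51.6-fold), a further glycosyltransferase, cdh6 (at least 48.2-fold) and fgf24 (at least 33.5-fold). Higher were esrrgb (at least 13.8-fold), an estrogen-related receptor, with 0 counts in the control, and acot18 (66.4-fold, 18.4 to 548). There were 971 genes at least 2-fold lower and 1660 at least 2-fold higher. The fits with 1 library fewer gave 514 lower and 1165 higher genes without Cocktail 4 replicate 1, 587 and 1157 without its replicate 2, 631 and 1022 without control replicate 1, and 627 and 1003 without control replicate 2. Of 14 genes named by rule, 11 were called whichever library was left out; 1 without Cocktail 4 replicate 1, 0 without Cocktail 4 replicate 2, 3 without control replicate 1 and 2 without control replicate 2 were lost (adjusted p up to 0.139).

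For Cocktail 5, ctdspl3 stood at 13.2% of the other cocktails (-2.92 ± 0.21), rbm25b at 13.8% (-2.86 ± 0.24) and rbbp5, a subunit of histone H3K4 methyltransferase complexes, at 16.5% (-2.60 ± 0.25). Lower as well were usp1 (-1.63 ± 0.19), naa40 (-1.69 ± 0.20), a name borne by several genes, emc6 (-1.43 ± 0.20), of the ER membrane complex, and nfyc (-1.31 ± 0.21), a subunit of the CCAAT-binding factor NF-Y (adjusted p at most 0.00271). In all, 10 genes were at least 2-fold lower than in the other cocktails and 9 of these at least 2-fold lower than in the control too, with a median of 31.0%. Leaving out replicate 1 or replicate 2 gave 6 and 6 genes; nfyc was lost in both fits (adjusted p = 0.0839 and 0.109), as were dap1b (at least 0.145) and unc45b (at least 0.269).

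Compared with the control, Cocktail 5 had 504 genes at least 2-fold lower and 1361 at least 2-fold higher. At 0 counts in the cocktail were fetub (at least 70.7-fold) and si:dkey-205h13.2 (at least 47.5-fold), and at 0 counts in the control atp6ap1lb (at least 27.7-fold). These 3 genes of the 14 named by rule were called whichever library was left out. Others by the rule were pnocb (at least 23.8-fold) and syn1 (at least 15.3-fold), a synapsin, and, among the increases, acot18 (72.1-fold, 20 to 596); 10 without Cocktail 5 replicate 1, 9 without Cocktail 5 replicate 2, 10 without control replicate 1 and 9 without control replicate 2 were lost (adjusted p up to 0.229). The counts of calls were 230 lower and 998 higher genes without Cocktail 5 replicate 1, 189 and 799 without its replicate 2, 253 and 771 without control replicate 1, and 250 and 738 without control replicate 2.

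In Cocktail 6, usp1 was at 17.7% of the other cocktails (-2.50 ± 0.20) and nfyc at 23.0% (-2.12 ± 0.23), both of which were also lower in Cocktail 5. The tetraspanin gene tspan31 had -1.61 ± 0.20 and dap1b, a name borne by several genes, -1.53 ± 0.34 (adjusted p of all 4 at most 0.0483). The call of dap1b was lost in edgeR with the replicate block (adjusted p = 0.0734) and after thinning (0.0525). In all, 8 genes were at least 2-fold lower than in the other cocktails and 4 of these at least 2-fold lower than in the control too, with a median of 27.5%. Without replicate 1, 2 genes were called, and tspan31 and dap1b were lost (adjusted p = 0.0913 and 0.494). Without replicate 2, 3 were called and dap1b was lost (1.000).

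Against the control, 166 genes were at least 2-fold lower and 669 at least 2-fold higher in Cocktail 6. Among the genes named by rule, si:dkey-205h13.2 (at least 43.6-fold), dld (at least 19.4-fold), a Delta ligand, and soul3 (at least 17.2-fold) had 0 counts, and cd44a, a hyaluronan receptor, had -4.71 ± 1.38. Among the increases were atp6ap1lb (at least 16.4-fold), ptdss1b (47.7-fold, 13.2 to 393) and vasna (35.7-fold, 9.89 to 295). Leaving out 1 library gave 28 lower and 342 higher genes without Cocktail 6 replicate 1, 32 and 334 without its replicate 2, 42 and 288 without control replicate 1, and 55 and 267 without control replicate 2. Of the 14 named genes, 2 (ptdss1b and vasna) were called whichever library was left out; 11 without Cocktail 6 replicate 1, 11 without Cocktail 6 replicate 2, 11 without control replicate 1 and 10 without control replicate 2 were lost (adjusted p up to 0.309).

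For Cocktail 7, qrich1 stood at 11.6% of the other cocktails (-3.11 ± 0.34) and ilf3a, a double-stranded RNA-binding protein, at 20.5% (-2.28 ± 0.22). Lower too were ube2g1a (-1.72 ± 0.19), a ubiquitin-conjugating enzyme, ddx39ab (-1.56 ± 0.18) and ddx3xa (-1.44 ± 0.24), both RNA helicases, xpc (-1.42 ± 0.22), of nucleotide excision repair, and efna2a (-2.87 ± 0.62), an ephrin (adjusted p at most 0.0269). In all, 28 genes were at least 2-fold lower than in the other cocktails and 9 of these at least 2-fold lower than in the control too, with a median of 20.5%. The counts were 8 without replicate 1 and 12 without replicate 2. In these fits xpc (adjusted p = 0.0836 and 0.103) and ddx3xa (0.105 and 0.115) were lost, and efna2a was lost without replicate 2 (0.387).

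Against the control, Cocktail 7 had 243 genes at least 2-fold lower and 656 at least 2-fold higher. At 0 counts were zgc:91890 (at least 18.5-fold), her7 (at least 23.3-fold), a hairy-related repressor, eve1 (at least 24.0-fold) and dld (at least 17.6-fold), and among the increases were atp6ap1lb (at least 18.4-fold), apc2 (at least 13-fold) and ptdss1b (30.7-fold, 8.50 to 253). With 1 library fewer there were 73 lower and 364 higher genes without Cocktail 7 replicate 1, 137 and 472 without its replicate 2, 62 and 286 without control replicate 1, and 76 and 281 without control replicate 2. Of the 14 named genes, 2 (zgc:91890 and ptdss1b) were called whichever library was left out; 11 without Cocktail 7 replicate 1, 10 without Cocktail 7 replicate 2, 12 without control replicate 1 and 12 without control replicate 2 were lost (adjusted p up to 0.243).

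In Cocktail 8, rbm7, an RNA-binding protein of the nuclear exosome targeting complex, was at 11.5% of the other cocktails (-3.12 ± 0.22), and ago4, an argonaute, at 17.8% (-2.49 ± 0.29). The maternal linker histone gene h1m had -1.70 ± 0.19 and pttg1, the securin gene, -1.77 ± 0.24 (adjusted p of all 4 at most 0.000579). In all, 13 genes were at least 2-fold lower than in the other cocktails and 4 of these at least 2-fold lower than in the control too, with a median of 22.8%. Leaving out replicate 1 gave 6 genes, without pttg1 (adjusted p = 0.0953), and leaving out replicate 2 gave 7.

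The comparison of Cocktail 8 with the control gave 327 genes at least 2-fold lower and 918 at least 2-fold higher. By the rule, frk (at least 16.8-fold), a kinase, lingo2b (at least 15.7-fold), anxa1c (at least 14-fold), an annexin, and cahz (at least 13.5-fold), a carbonic anhydrase, had 0 counts. With the replicate block in edgeR, anxa1c just missed the threshold (adjusted p = 0.0502). Among the increases were atp6ap1lb (at least 29.1-fold), vasna (68.5-fold, 19.0 to 566) and ptdss1b (41.4-fold, 11.4 to 342), the 3 of 14 named genes that were called whichever library was left out. Of the rest, 10 without Cocktail 8 replicate 1, 10 without Cocktail 8 replicate 2, 10 without control replicate 1 and 10 without control replicate 2 were lost (adjusted p up to 0.219). Counts of calls were 74 lower and 499 higher genes without Cocktail 8 replicate 1, 297 and 686 without its replicate 2, 101 and 420 without control replicate 1, and 120 and 420 without control replicate 2.

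Many genes were lower than the control in several cocktails. In all 8 cocktails 59 genes were called at least 2-fold lower. Taken in order of their mean log2 change, with the fold by which the mean CPM of the cocktails lay below the control, the first 15 included slco1d1 (21.9-fold), cdh6 (28.1-fold), add3b (22.0-fold), b3gnt5a (12-fold), evpla (24.0-fold), krt5 (21.3-fold), CR854839.1 (13.4-fold), si:ch211-98n17.5 (13.8-fold), mttp (11.5-fold), krt97 (17.3-fold), cyp2x6 (10.8-fold), tmem154 (9.94-fold), znf185 (9.09-fold) and hsd17b14 (8.37-fold). Among them krt5 and krt97 are keratins, evpla a plakin and mttp a lipid transfer protein. Of 1785 genes lower in at least 1 cocktail, 1125 were lower in 2 or more, against 589.5 for independent lists of these sizes. In 20 simulations of unchanged groups against the same controls, at most 1 gene was lower in 2 or more. A median of 1 gene was called lower in any cocktail there, so these simulations cannot gauge overlap between lists of the real sizes. Part of the excess over independent lists may come from the shared controls, which could not be split so that each part kept 2 libraries. The count was 690 without control replicate 1 and 679 without control replicate 2.

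Against the other cocktails, 122 genes were lower in at least 1 cocktail, 25 in 2 or more and 4 in 3 or more. The deubiquitinase gene usp1 was lower in Cocktails 4, 5 and 6, and ptbp1a, a splicing repressor, tgm2b, a transglutaminase, and CABZ01065076.1 in Cocktails 1, 3 and 4. The Cocktail 1 calls of ptbp1a, tgm2b and CABZ01065076.1 were lost without its replicate 1, the library that stood apart. So were those of hsd17b14 and zgc:153018, shared with Cocktail 4. Such a loss may also reflect the fewer libraries. Among genes shared by a pair were bckdk and tarbp2 (Cocktails 2 and 3), papolg and ppp4r2a (1 and 3), alg3 (1 and 2), rbm25b, rbbp5, ctdspl3, naa40 and emc6 (4 and 5), rnf128a (4 and 6), nfyc (5 and 6), and bzw1a, kdm4ab and snupn (7 and 8). Of these, bzw1a, kdm4ab and snupn were not called at least 2-fold lower than the control in Cocktail 7 or 8. Of 28 pairs of cocktails, 9 shared a gene. Independent lists would share at most 0.0675 genes per pair, and 0 were shared in 20 simulations of unchanged groups. No gene was lowered in these simulations, so they show only how rarely false calls coincide. A gene lowered in a cocktail also lowers the reference of the others, so these comparisons are not independent. The genes outside the naming rule were chosen after their values were seen.

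**Figure D3:**
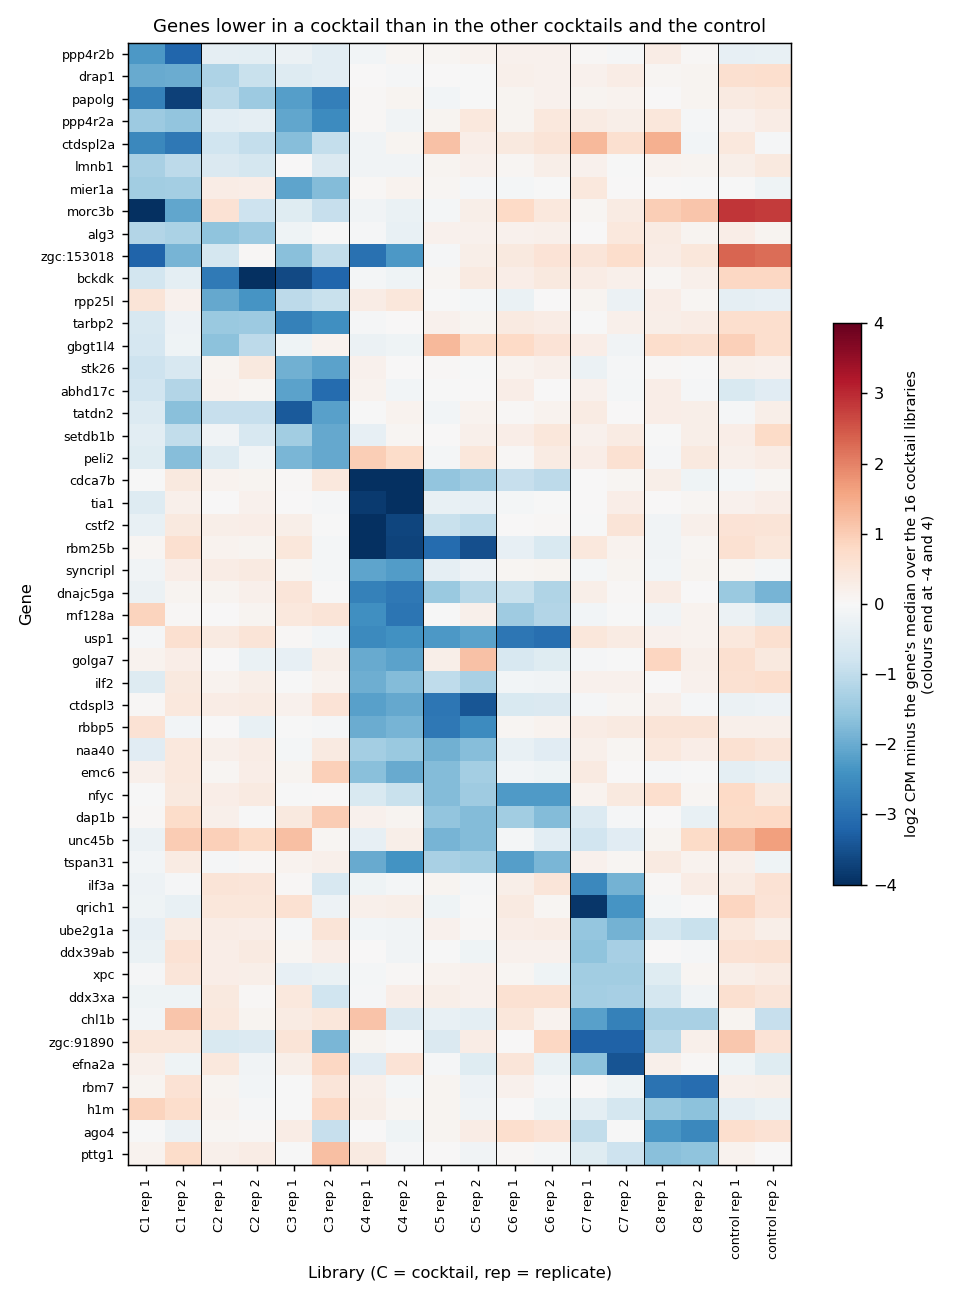
Log2 CPM of 50 genes lower in a cocktail against both references (rows) in the 18 libraries (columns), minus the gene's median over the 16 cocktail libraries; colours end at -4 and 4. By the way genes were chosen, low levels stand in both libraries of the cocktail for which each was named. An example is cdca7b in Cocktail 4 (5.52% of the other cocktails). Some genes were lower in further cocktails too, as cdca7b was in Cocktails 5 (-1.58 and -1.42) and 6 (-0.918 and -1.05).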

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

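Tests of the control libraries as a batch, the thinning and the value without Cocktail 1 replicate 1 were chosen only after the results were seen. Unmapped reads, which enter no comparison, made up 29.7% of reads on average over the 16 cocktail libraries, 19.3 percentage points above the control (two-sided exact permutation p = 0.00654, taking libraries as independent). The change of the enveloping layer list against the control differed between the 8 cocktails by more than between their replicates (permutation p = 0.0105, adjusted p = 0.0420 over 16 lists; permutation p = 0.00206 without Cocktail 1 replicate 1).

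The pattern weighed is the gap between cocktail and control libraries, with enveloping layer and yolk syncytial layer genes lower and oocyte genes higher in the cocktails. The values argue against lower depth as the whole cause. After thinning every library to the smallest total, 90.3% of the genes called for all cocktails were still called in the same direction. A batch difference of the controls cannot make cocktails differ from one another, as they did in the enveloping layer median (permutation p = 0.0105). That difference between cocktails does not bear on whether such a batch made the gap to the control. A batch set apart from all others may still hold both controls, because 16 of 16 cocktail libraries lay below both controls in the enveloping layer median, and this cannot be told apart from an effect of what the cocktail embryos received. The library with more unmapped reads had the lower enveloping layer median in 4 of 8 cocktails (exact 95% interval 15.7% to 84.3%; r = 0.184, exact permutation p = 0.680, adjusted 0.680; rho = 0, p = 1; r = 0.264 without the 2 farthest), a value too imprecise to exclude library quality, which between groups moves with the cocktails. Slower development of the cocktail embryos is a hypothesis that stays open: replicate differences in the enveloping layer and oocyte medians had r = -0.455 over 8 cocktails (exact permutation p = 0.267, adjusted 0.356 over 4 relations; rho = -0.190, p = 0.665; r = 0.0144 without the 2 farthest).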

How the results depend on the processing

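Thinning, leaving out Cocktail 1 replicate 1 from the list tests and leaving out cocktail libraries from the comparison of all cocktails were chosen only after the results were seen. The numbers of lists passing, unlike the counts of genes, were recomputed only without either control library and without Cocktail 1 replicate 1. Their ranges below do not cover the other libraries. Of 2962 values of named genes under an alternative, 2556 kept direction and side of the threshold, 384 lost the call (325 without 1 library, 34 with TPM, 9 with DESeq2), 22 gained it and 0 reversed; DESeq2 gave 38 no adjusted p. RLE size factors moved 0 of 29 counts of calls by over 1.5 times, and a 1.5-fold minimum and thinning, run only on the 2 counts for all cocktails, moved 0 of these. Where a count moved, the cause was not tested, beyond the fewer libraries or other genes that a setting leaves. Depth limits the folds of genes at 0 counts, which are bounds.

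Leaving out each library in turn, genes lower than the control ranged over 741 to 1613, 171 to 181, 618 to 1363, 514 to 631, 189 to 253, 28 to 55, 62 to 137 and 74 to 297 in Cocktails 1 to 8, higher genes over 1011 to 2155, 444 to 572, 1046 to 1655, 1003 to 1165, 738 to 998, 267 to 342, 281 to 472 and 420 to 686, and genes lower than the other cocktails over 10 to 684, 2 to 4, 14 to 381, 15 to 16, 6 in both fits, 2 to 3, 8 to 12 and 6 to 7. For all cocktails, lower genes ranged over 876 to 2668 and higher genes over 1009 to 2489, genes lower in 2 or more cocktails over 679 to 1403, lists passing for all cocktails over 7 to 8 and for single cocktails over 52 to 67.

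With DESeq2, genes lower than the other cocktails numbered 111 in Cocktail 1, 11 in 2, 59 in 3, 50 in 4, 20 in 6, 81 in 7 and 25 in 8, and genes lower than the control 255 in Cocktail 6. With no filter the first were 282 in Cocktail 1, 14 in 2, 100 in 3, 127 in 4, 16 in 5, 27 in 6, 117 in 7 and 45 in 8, the second 712 in Cocktail 2, 362 in 6, 480 in 7 and 559 in 8, and the share of higher calls was 57.1% in Cocktail 2, 68.7% in 6 and 60.2% in 7. With only the groups compared in the fit, lower genes against the control were 708 in Cocktail 1, 921 in 2, 1075 in 5, 652 in 6, 621 in 7 and 675 in 8, higher genes 798 in Cocktail 1 and 1098 in 6, and the share of higher calls 53.6% in Cocktail 2, 49.0% in 3, 60.2% in 5, 62.7% in 6, 56.1% in 7 and 59.3% in 8; with all libraries these shares were 67.3% in Cocktail 2, 60.0% in 3, 73.0% in 5, 80.1% in 6, 73.0% in 7 and 73.7% in 8. With limma on TPM, genes lower than the other cocktails were 138 in Cocktail 1 and 21 in 8, and for all cocktails 1209 genes were lower. With no fold minimum, 842 in Cocktail 5 and 508 in 8 were lower than the control. With an estimated correlation 1 list passed for all cocktails and 0 for single cocktails.

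The replicate numbers did not pair the samples: over 36 pairs of groups the correlation of deviations ran from -0.124 to 0.125, with 1 over 0.1. With the replicate block, 1925 genes were lower and 2125 higher for all cocktails, 7 and 54 lists passed, and 0 counts moved by over 1.5 times; 9 named calls were lost.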

Other observations

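The comparison of genes higher than in the other cocktails, the test of genes shared by cocktails against a common set of transcripts, the absolute correlations and those without Cocktail 1 replicate 1, and the tests of a mislabelled library and of zygotic transcripts in that library were chosen only after the results were seen. Some genes were higher in a cocktail than in the others, counts that were not refitted without single libraries. In Cocktail 6, 35 genes were at least 2-fold higher than in the other cocktails, among them cyt1 (3.00 ± 0.47), a keratin, hsd17b14 (2.29 ± 0.29) and znf185 (2.21 ± 0.33) (log2 ± SE, n = 2; edgeR). Also among them were b3gnt5a, a glycosyltransferase, with 23.5 ± 4.44 CPM (SD, n = 2) against a mean of 7.57 CPM in the other cocktails, and zgc:110333, with 20.7 ± 0.888 CPM (SD, n = 2) against a mean of 6.16 CPM in the other cocktails, for which no fold is given because both had 0 counts in Cocktail 4. Of these 35, 8 were called lower than in the control, with no minimum fold, and 1 at least 2-fold higher. Their median change against the control was -0.991 log2 units. The genes named here all stood below the control mean: cyt1 (11.5 against 44.5 CPM), hsd17b14 (29.4 against 105) and znf185 (36.9 against 139). The control means of b3gnt5a and zgc:110333 were 114 and 65.6 CPM. Being higher than in the other cocktails therefore does not mean a rise over the control. In Cocktail 7, 52 genes were higher, with 10 of them called lower, with no minimum fold, and 3 at least 2-fold higher than in the control. One of them was fetub, with 5.12 ± 0.658 CPM (SD, n = 2) against a mean of 0.281 CPM in the other cocktails and 0 counts in 4 of the 8 cocktails. Its control mean was 29.7 CPM, above that of Cocktail 7.

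Of the 36 genes higher in Cocktail 5 than in the other cocktails, 14 were at least 2-fold higher than in the control. The 36 included idi1 (1.48 ± 0.22), of isoprenoid synthesis, and pcyt2 (1.41 ± 0.18), of phosphatidylethanolamine synthesis. They also held bckdha (1.17 ± 0.15), a subunit of the branched-chain ketoacid dehydrogenase, and rnf126 (1.18 ± 0.16). Replicates lay apart in these genes: idi1 had 96.9 ± 54.3 CPM (SD, n = 2) against 57.5 CPM in the control. For pcyt2 the values were 275 ± 99.7 against 78.8 CPM, for bckdha 257 ± 87.0 against 133, and for rnf126 328 ± 85.1 against 187.

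Of the 25 genes lower than the other cocktails in several cocktails, 19 were shared only among Cocktails 1 to 3, only among 4 to 6, or by 7 and 8, a grouping noticed in the data. A developmental state common to those cocktails stays open for these: their median r with the enveloping layer median over the 16 cocktail libraries was -0.00630 (-0.458 to 0.566 across genes), low enough to meet the bound set for excluding it, but that bound took the genes to follow the state in the same direction, and the median absolute r was 0.171, or 0.335 without Cocktail 1 replicate 1. For the 6 genes shared by Cocktail 4 with Cocktail 1 or 3 or both, CABZ01065076.1, hsd17b14, kdm2ba, ptbp1a, tgm2b and zgc:153018, the median r was 0.775 (0.549 to 0.847; median 0.897 without that library), which decides nothing, since they were chosen as lower in Cocktails 1, 3 or 4, and these had the lowest enveloping layer medians (-5.07, -3.13 and -3.38; -2.25 to -1.59 in the others). That gRNAs of neighbouring cocktails match the same transcripts is a candidate explanation for the 19. It cannot be told from these data because the gRNA sequences are not given in the sources used here. Not all of the 19 were called at least 2-fold lower than the control as well. In Cocktails 7 and 8, bzw1a, kdm4ab and snupn were not, nor was rnf128a in Cocktail 6. For bzw1a the control mean was 158 CPM, against 557, 636, 548 and 521 CPM in Cocktails 1 to 4. Being lower than the other cocktails therefore need not mean a fall below the control. Genes in these correlations are not independent of one another.

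Cocktail 1 replicate 1 lay apart from all other libraries on the first principal component. The tables argue against a wrong label, since most genes lower in the other Cocktail 1 library than in the other cocktails were lower here too (median -1.21 on the log2 scale, with sc:d217 at 0.41 and peli2 at -0.44 the highest). Its enveloping layer median lay -3.92 log2 units from that of replicate 2 and its oocyte median 0.27, as embryos further from the control along this axis might show. The oocyte difference was close to that between the Cocktail 4 replicates (0.263), where the enveloping layer difference was 0.138. It therefore does not set this library apart. Its ubiquitous early zygotic median of -6.0, against -1.06 to -0.22 in the other 15 cocktail libraries, is what few zygotic transcripts in this library would give. That reading was drawn from the same values, so it is no separate test. What would lower such transcripts was not tested.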
